A study of Mus musculus with 8 samples.

How the data were processed

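Gene expression was measured on 8 microarrays in mouse bone marrow progenitors cultured for 4 days. Per the labels' protocols, lymphoid primed multipotent progenitors of Tcf1-deficient and wildtype mice were seeded on OP9-DL4 cells, a stromal line that presents a Notch ligand, with Flt3 ligand at 5 ng/ml and a second cytokine. CD45.2-positive cells were then sorted as lineage-negative (Mac1, Gr1, Thy1 and CD25 negative) or as T lineage (Thy1 and CD25 positive). The lineage-negative cells came from 3 mice of each genotype. T lineage cells came from 2 wildtype replicates, and per the labels no such cells developed from deficient progenitors. Per the labels' protocols, 10 ng of total RNA per array was amplified with a whole-transcript kit and labelled with biotin. The mice are labelled as of a line kept on a mixed background.

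The deposited table holds log2 values per probeset. Per the submitters' processing notes, the authors made these values with RMA (robust multi-array averaging, which corrects background, normalises the arrays together and summarises the probes of a set) in Partek 6.5. The log2 scale was read from the range of the values themselves. Other options of the processing, a scan date and the genome build of the array are not given in the sources used here. Array medians lay between 6.85 and 6.91. A detection level above background was not used here, and the number of arrays limits the precision.

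The table held 35399 probesets. Of these, 11989 were listed without a gene and 1621 with several genes, and both kinds were left out. The remaining 21789 probesets, each with exactly 1 gene symbol, covered 19938 genes, of which 999 had several probesets. The gene identifier matched the reference annotation for 99.6% of the tested probesets (21698). The transcript of the targeted gene was not analysed here, so the genotype labels were not checked against it.

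Differences were computed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). All 8 arrays were fitted together as 3 groups with a shared spread and 5 residual degrees of freedom. The comparisons were deficient minus wildtype lineage-negative cells, T lineage minus wildtype lineage-negative cells and T lineage minus deficient lineage-negative cells. Tests were two-sided, p was adjusted by Benjamini-Hochberg over the 21789 probesets, and an adjusted p under 0.05 was a call. Counts are of probesets unless genes are stated. Values are log2 differences with their standard error (SE), and group levels are means with the standard deviation (SD).

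The gene lists, the tests, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The 22 lists were T lineage transcription factors, T cell receptor (TCR) complex and proximal signalling, V(D)J recombination, Notch target genes, Notch receptors and pathway machinery, Wnt and beta-catenin target genes, haematopoietic stem and progenitor genes, lymphoid priming genes, granulocyte and monocyte genes, B lineage genes, NK and innate lymphoid genes, dendritic cell and MHC class II genes, mast cell and basophil genes, erythroid and megakaryocyte genes, stromal cell genes, mitotic cell cycle, DNA replication, interferon response, immediate early and heat shock genes, apoptosis regulators, homing and chemokine receptors, and sex-linked genes. They named 468 symbols, of which 422 were measured, and some genes stand in several lists. Each list was tested against all other probesets with camera at its preset correlation of 0.01 between genes, adjusted over the 66 tests of 22 lists in 3 comparisons. Camera with a correlation estimated from the data was the alternative. fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, was computed beside it, with its form for change in either direction. The members of a list past the threshold were counted over all probesets and also with p adjusted over the list alone.

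Named genes were, for the first and second comparisons, the 12 with the largest rise and the 12 with the largest fall among calls whose arrays did not overlap between groups, and 5 and 5 for the third. A fixed panel of lineage genes was added whatever it showed, with up to 4 called members of each list of smallest p, or the 2 of largest change where none was called. A gene with several probesets was named by the one of smallest p. Thy1 and Il2ra (CD25) separated the gates and Itgam (Mac1) and Ly6g (Gr1) were gated out, so between gates they check the sort. The overlap of comparisons that share arrays was set against n1 times n2 over N and against 100 simulations of unchanged groups with the same sharing. Counts at an unadjusted p under 0.05 were also set against 100 simulations that kept the T lineage differences, added after the data were seen.

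The fit was tested on simulated data in 10 runs with 200 of the 21789 probesets changed. Between the lineage-negative groups it recovered 89.0% of changes of 0.5, 99.9% of changes of 1 and 100% of changes of 2 (log2), and 4.56% of its calls were false. Between T lineage and wildtype lineage-negative cells it recovered 76.4%, 99.7% and 100%, with 5.59% of calls false. Adjusted p is less strict where many probesets change, so recovery would be lower in a comparison with few changes. These shares therefore do not give the power of the genotype comparison. Camera found a list shifted by 0.2 in 10 of 10 runs, called lists in unchanged data 2 times and called another of the 22 lists 3 times. Genes varied independently in all these runs. The runs therefore do not show how often genes that vary together give false calls, of lists above all.

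The alternatives were a fit of only the groups compared, dropping the dimmest 40% of probesets, using all probesets, averaging the probesets of a gene, a second quantile normalization, median centring, eBayes with trend and robust settings, array weights, a replicate block, the estimated correlation for lists, and leaving out each array in turn. A covariate for the sex of the mice, read from sex-linked transcripts, and leaving the gate genes Thy1, Il2ra, Itgam and Ly6g out of the lists were added after the data were seen. Apart from Il2ra between the genotypes, calls lost or gained with the replicate block are given together under how the results depend on the processing. They are not repeated beside each gene or list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.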

Results

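The 8 arrays fell into 3 groups: Tcf1-deficient lineage-negative cells (3 mice), wildtype lineage-negative cells (3 mice) and wildtype T lineage cells (2 replicates), each taken after 4 days on the Notch ligand stroma. Tcf1 is a transcription factor of the T lineage. The comparisons ask how progenitors that lack it differ from wildtype progenitors after Notch stimulation, and how far either stands from the T lineage cells that arise only in the wildtype cultures. Arrays of the same group correlated across probesets with r from 0.995 to 0.997, and lineage-negative with T lineage arrays with r from 0.973 to 0.983, where probesets are not independent replicates. The first principal component held 70.1% of the variance. It placed the T lineage arrays at 46.5 and 41.0 and the lineage-negative arrays of both genotypes between -20.7 and -8.07.

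The transcripts of the surface proteins that separate the gates, Thy1 and Il2ra, were higher in T lineage cells. Thy1 stood at 12.20 ± 0.45 (SD, n = 2) in T lineage cells, 8.46 ± 0.27 (SD, n = 3) in wildtype and 8.48 ± 0.06 (SD, n = 3) in deficient lineage-negative cells. Il2ra, which encodes CD25, stood at 12.23 ± 0.01 (SD, n = 2) in T lineage cells. Itgam (Mac1), although its protein was gated out of the lineage-negative cells, was lower in T lineage than in wildtype lineage-negative cells by a log2 difference of -1.41. Ly6g (Gr1) stood between 4.69 and 4.79 in the 3 groups.

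Deficient and wildtype lineage-negative cells were close to each other, and 1 gene passed the test between them. Il2ra, the alpha chain of the interleukin-2 receptor, was 2.03-fold lower in deficient cells (log2 difference -1.02, SE 0.10, limma adjusted p = 0.0283), although both groups were sorted as CD25 negative. Its level was 5.95 ± 0.23 (SD, n = 3) in deficient and 6.97 ± 0.06 (SD, n = 3) in wildtype cells, with all 3 deficient arrays below all 3 wildtype arrays. None of the other T lineage genes of the panel passed. Gata3 differed by 0.11, Bcl11b by 0.07, Lef1 by -0.07, Cd3e by 0.02, Cd3g by 0.27, Thy1 by 0.02, Rag1 by 0.18 and Rag2 by 0.16, each at an adjusted p of 0.999.

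Among Notch target genes, 1 of 16 fell (Il2ra), 0 rose and 15 did not pass. Hes1, a repressor switched on directly by Notch, had a log2 difference of 0.61 (SE 0.11, adjusted p = 0.198), with levels of 7.90 ± 0.18 (SD, n = 3) in deficient and 7.28 ± 0.13 (SD, n = 3) in wildtype cells. Adjusted over the list alone, 1 Notch target was higher and 1 lower. Notch1 (0.35), Dtx1 (0.09), Nrarp (0.13), Notch3 (0.07) and Ptcra (-0.02) had adjusted p of 0.979 or more. The list as a whole did not pass (mean 0.05, camera adjusted p = 0.0526). It passed without deficient array 1 (0.0243), wildtype lineage-negative array 1 (0.0463), T lineage array 1 (0.0407) or T lineage array 2 (0.0377), without the dimmest 40% of probesets (0.0155), with a second quantile normalization (0.0481), with array weights (0.0385) and with the sex covariate (0.022), over a range of 0.0155 to 0.463 with Il2ra kept. Leaving Il2ra out was chosen after the data were seen, and the mean of the other 15 was then 0.13 (camera adjusted p = 0.00172). Both genotypes were sorted through the same gate, and Il2ra was the 1 called member and lay lower. Dropping it raises the list in any case, so this p is no support for a rise. No other alternative and no regrouping of arrays was run on these 15. In the Notch receptors and pathway machinery 0 of 21 genes passed (list adjusted p = 0.169), with Mfng, a glycosyltransferase that modifies Notch, at 0.22 (adjusted p = 0.827). That list passed without deficient array 1 (0.0272) or wildtype lineage-negative array 3 (0.0222).

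For antigen-presenting and myeloid genes the means of whole lists were lower in deficient cells while no member passed over all probesets. Camera called 6 lists between the genotypes, and 3 to 8 lists when the same arrays were regrouped across the genotypes. The number of list calls therefore does not set the genotypes apart. The dendritic cell and MHC class II list had a mean difference of -0.22 (camera adjusted p = 8.91e-08). Its adjusted p = 0.353 with an estimated correlation, and without wildtype lineage-negative array 3 its mean was -0.13 (0.00149, range over alternatives 3.31e-11 to 0.353). Of its 23 genes 0 passed, and 8 were lower when adjusted over the list alone. Examples were Ccr9, a homing receptor (-0.64, adjusted p = 0.778), Cd209a, a lectin of dendritic cells (-0.59, 0.65), and Bst2, an interferon-induced membrane protein (-0.47, 0.198). The granulocyte and monocyte list had a mean of -0.13 (adjusted p = 0.0112, and adjusted p = 0.61 with an estimated correlation). Of its 37 genes 0 passed and 1 was lower when adjusted over the list alone. S100a9, a calcium-binding protein of granulocytes, differed by -0.87 (adjusted p = 0.778). The interferon response list had a mean of -0.14 (adjusted p = 0.000819, and adjusted p = 0.463 with an estimated correlation), with 0 of 22 genes past the test, 1 lower when adjusted over the list alone, and Stat2 at -0.38 (adjusted p = 0.827). These shifts rested on single arrays in part. Without deficient array 2 or wildtype lineage-negative array 3 the granulocyte and monocyte list had adjusted p of 0.127 and 0.908, with a mean of -0.03 without the latter and -0.24 without wildtype lineage-negative array 1 (range over alternatives 2.58e-08 to 0.908). The interferon list then had 0.0837 and 0.15, with means of -0.07 without wildtype lineage-negative array 3 and -0.21 without array 1, and 0.0508 without the dimmest 40% of probesets (range 8.93e-07 to 0.463).

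The limit from regrouped arrays, which gave 3 to 8 list calls against 6 for the real groups, holds for the next lists too. Stem and progenitor genes were higher as a list in deficient cells, with a mean of 0.10 (adjusted p = 9.72e-05, and adjusted p = 0.353 with an estimated correlation). The mean was 0.15 without deficient array 1 and 0.06 without deficient array 3 (adjusted p = 3.07e-06 and 0.014, range over alternatives 3.07e-06 to 0.353). Of 25 genes 0 passed, also when adjusted over the list alone. Examples were Angpt1, a ligand made by early progenitors (0.37, adjusted p = 0.65), and Kit, the receptor of stem cell factor (0.36, 0.701). The stromal cell list had a mean of 0.06 (adjusted p = 0.0187, and adjusted p = 0.606 with an estimated correlation), with 0 of 31 genes past the test and 1 higher when adjusted over the list alone. Sparc, a matrix protein whose gene lies 3.15 Mb from the targeted locus, differed by 0.54 (adjusted p = 0.0997). The mitotic cell cycle list had a mean of -0.06 (adjusted p = 0.0142, and adjusted p = 0.606 with an estimated correlation) with 0 of 24 genes past the test. Without deficient array 2 or wildtype lineage-negative array 3 the stromal list had adjusted p of 0.378 (mean 0.02) and 0.168, and 0.0948 with array weights (range over alternatives 0.0021 to 0.606). The mitotic list had 0.62 (mean -0.03) and 0.15 without these arrays, 0.000614 without wildtype lineage-negative array 2 (mean -0.09), 0.117 without wildtype lineage-negative array 1 and 0.0904 with array weights (range 0.000614 to 0.62).

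The other lists did not pass between the genotypes, and no member of theirs passed. Adjusted p was 0.978 for T lineage transcription factors, 0.287 for the TCR complex and proximal signalling, 0.7 for V(D)J recombination, 0.287 for Wnt and beta-catenin target genes, 0.759 for lymphoid priming genes, 0.693 for B lineage genes, 0.13 for NK and innate lymphoid genes and 0.978 for mast cell and basophil genes. It was 0.841 for erythroid and megakaryocyte genes, 0.107 for DNA replication, 0.827 for immediate early and heat shock genes, 0.586 for apoptosis regulators, 0.768 for homing and chemokine receptors and 0.586 for sex-linked genes. Examples were Cd28, a costimulatory receptor of T cells (-0.84, adjusted p = 0.522), Blnk, a B cell adaptor (-0.61, 0.466), Fasl, a death ligand (0.63, 0.831), Klrd1, an NK receptor chain (-0.47, 0.491), and Lgr5, a Wnt target (-0.33, 0.583). Adjusted over the list alone, the TCR list had 2 higher and 2 lower genes, the Wnt list 1 lower, lymphoid priming 1 higher, B lineage 1 lower and NK genes 2 lower. Several lists passed under an alternative. DNA replication passed without deficient array 2 (0.0175) or wildtype lineage-negative array 1 (0.0377), and also without the dimmest 40% of probesets (0.0438), with a second quantile normalization (0.0238) and with array weights (0.0176), over a range of 0.0175 to 0.829. NK genes passed without wildtype lineage-negative array 1 (0.0463) and Wnt targets without deficient array 2 (0.0273). Mean and median differed in sign for T lineage transcription factors, V(D)J recombination, lymphoid priming, erythroid, immediate early, apoptosis and homing lists, all within 0.05 of 0, and the direction tested also differed from the mean for lymphoid priming and homing genes.

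Over all probesets, 1071 had an unadjusted p under 0.05 between the genotypes where chance gives 1089, and 9 had an adjusted p under 0.1. The median size of the difference was 0.06 and the median SE 0.08. The call of Il2ra was lost without deficient array 3 (adjusted p = 0.132), wildtype lineage-negative array 2 (0.138) or wildtype lineage-negative array 3 (0.219), with median centring (0.052), with a replicate block (0.151) and with all probesets (0.268), over a range of 0.00539 to 0.268, while its difference stayed between -1.13 and -0.90. The number of calls was 4 without deficient array 1, 0 without deficient array 3, 12 without wildtype lineage-negative array 1, 0 without wildtype lineage-negative array 3 and 2 without either T lineage array. With fry, 0 of the 22 lists moved on balance one way at an adjusted p under 0.05 and the smallest was 0.106, for apoptosis regulators. Tested for change in either direction, 6 passed: Notch targets (0.000211), NK genes (0.007), stromal genes (0.0166), dendritic cell genes (0.0217), interferon response genes (0.0254) and immediate early genes (0.0257). This form can rest on single members, and the Notch list holds Il2ra and the stromal list Sparc. Regrouped arrays were not tested with fry, so how often it passes lists there is unknown.

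**Figure D1:**
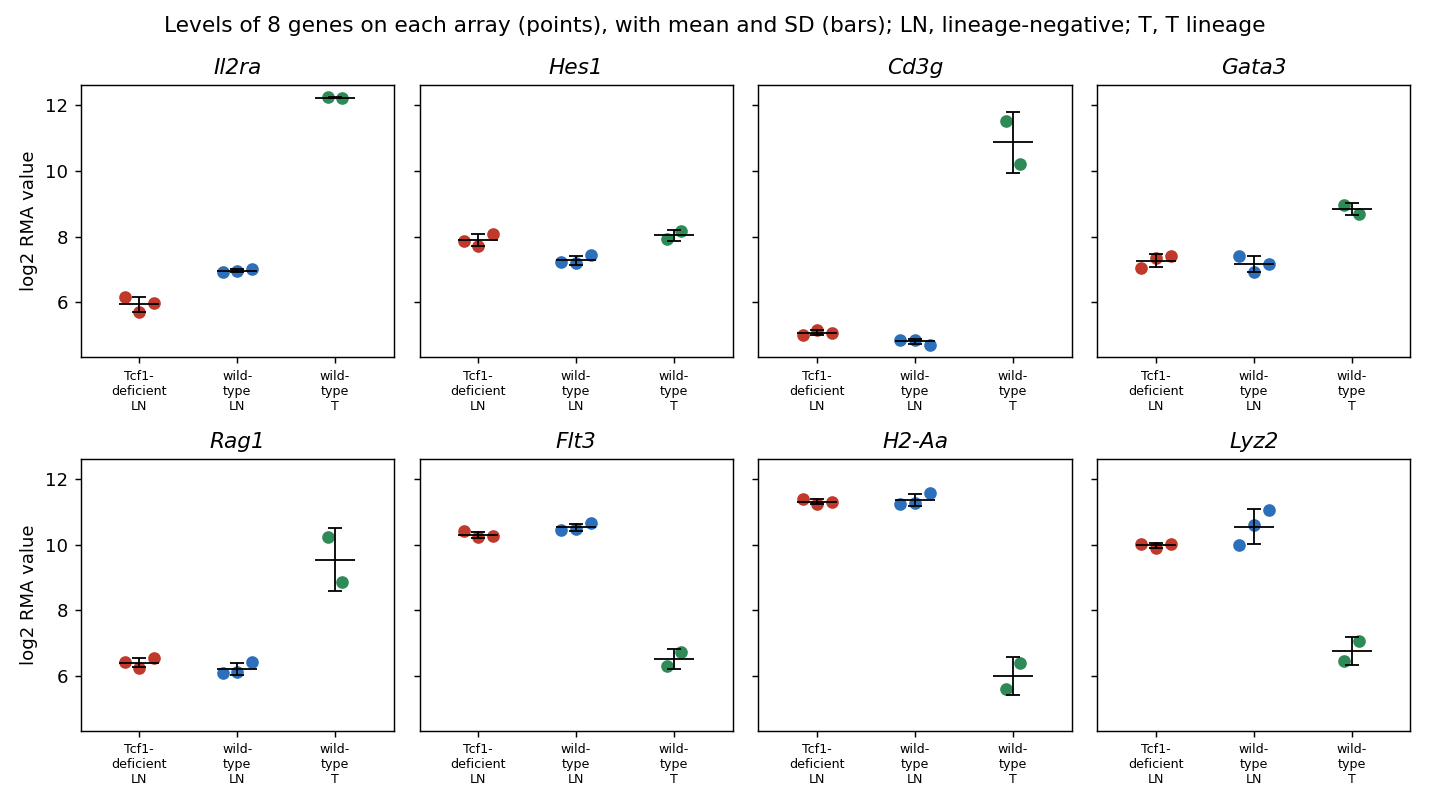
Levels of 8 genes (log2 RMA value, vertical axis) on each array of the 3 groups, with points for arrays and bars for the mean and SD. Il2ra stood at 5.95 in deficient and 6.97 in wildtype lineage-negative cells and at 12.23 in T lineage cells, while the other 7 genes did not pass between the genotypes.

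T lineage cells differed widely from wildtype lineage-negative cells. Of the T cell receptor and signalling genes 14 of 26 were higher, and of the dendritic cell and MHC class II genes 21 of 23 and of the granulocyte and monocyte genes 22 of 37 were lower. V(D)J recombination genes and stem and progenitor genes went both ways. No list passed with an estimated correlation. Of 21789 probesets 3928 passed, 1670 higher and 2258 lower (3723 genes, 1589 higher and 2142 lower, some in both). At least 2-fold were 145 higher and 519 lower. After a second quantile normalization the balance turned, with 2174 higher and 2006 lower. Cd3g, a chain of the T cell receptor complex, rose by 6.05 (SE 0.27), from 4.81 ± 0.08 (SD, n = 3) to 10.87 ± 0.92 (SD, n = 2). H2-Aa, an MHC class II chain, fell by 5.37 (SE 0.19), from 11.37 ± 0.19 (SD, n = 3).

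After Cd3g and the gating genes Il2ra (5.26) and Thy1 (3.75), the largest rises were those of Trgv1, a variable segment of the T cell receptor gamma locus (4.53), Fam20a (3.55), Rag1, a recombinase subunit (3.32), Plxdc2 (3.29), Gzma, a serine protease of killer cells (3.24), Akr1c12 (3.12), Cd3d, another chain of the T cell receptor complex (2.87), Ppic (2.86) and Khdc1a (2.80). The largest falls were those of Klrd1 (-5.71), H2-Aa, Nucb2 (-4.91), H2-Ab1, an MHC class II chain (-4.81), Cybb, the phagocyte oxidase subunit (-4.61), the protease Ctsh (-4.58), Hpgd, which degrades prostaglandins (-4.57), Clec9a, a lectin of dendritic cells (-4.54), S100a8 (-4.53), Ifi205 (-4.52), Mpeg1, a pore-forming protein of macrophages (-4.47), and Kynu, an enzyme of tryptophan breakdown (-4.44).

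T lineage transcription factors rose in 11 cases, fell in 3 and did not pass in 7 of 21. Gata3 rose by 1.68 (adjusted p = 2.26e-05), Ets1 by 1.29 and Bcl11b, a factor of T lineage commitment, by 0.51 (0.00114), while Id3, an inhibitor of E proteins, fell by 2.19. Adjusted over the list alone, 11 were higher and 4 lower, and the list rose with a mean of 0.21 (adjusted p = 0.0353, and adjusted p = 0.606 with an estimated correlation). The list call was lost without deficient array 2 (0.0541), wildtype lineage-negative array 2 (0.0501) or T lineage array 1 (mean 0.13, adjusted p = 0.128), over a range of 0.00687 to 0.606. Lef1, a factor of the same family as Tcf1, passed with 0.64 (adjusted p = 0.0408), which was 1.04 without T lineage array 2 and was lost without T lineage array 1 (0.24, adjusted p = 0.352), without any of the 3 wildtype lineage-negative arrays (0.108, 0.0593 and 0.1), without deficient array 1 (0.0543) or 2 (0.0515), and with only the 2 groups fitted (0.0708), over a range of 0.00056 to 0.352.

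Of 26 genes of the TCR complex and proximal signalling, 14 rose, 4 fell and 8 did not pass, also when adjusted over the list alone. Examples were Prkcq, a kinase of T cell activation (2.45), and the adaptor Lat (2.29), while Cd7, a surface protein of early lymphoid cells, fell by 3.08. The list rose with a mean of 0.64 (adjusted p = 0.00283, and adjusted p = 0.606 with an estimated correlation), and without the dimmest 40% of probesets its mean was 0.06 (adjusted p = 0.614), over a range of 5.66e-06 to 0.614. Dimness was ranked by the mean over all arrays, and Cd3g and Cd3d, dim outside T lineage cells, were among the dropped. Cd3e rose by 0.69 (adjusted p = 0.0218), which was lost without wildtype lineage-negative array 3 (0.0742) or T lineage array 1 (0.39, adjusted p = 0.217), over a range of 0.00403 to 0.217. Ptcra, the surrogate alpha chain of the receptor, differed by -0.06 (adjusted p = 0.726). Among V(D)J recombination genes 4 of 11 rose, 1 fell and 6 did not pass. These included Rag1, Rag2, the second recombinase subunit (1.16, and 0.76 without T lineage array 1), and Xrcc5, a subunit of the Ku repair complex (1.84), against Xrcc4, a ligation factor, which fell by 0.43. As a list they did not pass (mean 0.44, median -0.02 over probesets and 0.18 over genes, adjusted p = 0.339), and they passed without T lineage array 2 (0.0205). Adjusted over the list alone, 4 were higher and 2 lower.

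Notch target genes rose in 6 of 16 cases and fell in 0, and 10 did not pass. Hes1 rose by 0.75 (SE 0.12, adjusted p = 0.00145) and Nrarp, a feedback inhibitor of Notch, by 0.61 (0.00156), beside Il2ra, Gata3 and Bcl11b, which stand in this list too. Dtx1 (0.26, adjusted p = 0.132, but 0.0392 with the sex covariate), Notch1 (0.26, 0.325) and Notch3 (0.07, 0.634) did not pass. Adjusted over the list alone, 7 were higher and 0 lower, and the list rose with a mean of 0.67 (adjusted p = 0.00073, and adjusted p = 0.216 with an estimated correlation). Il2ra, whose protein defined the gate, made up much of this, and without it the mean was 0.37 (adjusted p = 0.00669), against a range of 0.000244 to 0.216 over the alternatives that kept it. In the Notch machinery 2 of 21 genes rose and 3 fell, also when adjusted over the list alone, with Mfng at 0.60 and the receptor Notch2 at -0.77 (list adjusted p = 0.646). Of 17 Wnt and beta-catenin targets 3 rose, 4 fell and 10 did not pass, and 4 were higher and 4 lower when adjusted over the list alone. Ccnd1, a cyclin of the early cell cycle (-1.58), and the adhesion receptor Cd44 (-1.09) fell (list mean -0.04, but median 0.07 and test upward, adjusted p = 0.978).

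Genes of dendritic cells and of granulocytes and monocytes were lower as lists. Of 23 dendritic cell and MHC class II genes 21 fell, 0 rose and 2 did not pass, with the same counts when adjusted over the list alone. Beside H2-Aa and H2-Ab1, H2-Eb1 (-3.33) and the integrin Itgax (-3.28) fell. The list mean was -2.14 (adjusted p = 1.1e-28, and adjusted p = 0.136 with an estimated correlation). Of 37 granulocyte and monocyte genes 22 fell, 1 rose and 14 did not pass, with 25 lower and 1 higher when adjusted over the list alone. Lyz2, the lysozyme of myeloid cells, fell by 3.79, from 10.55 ± 0.52 (SD, n = 3) to 6.76 in T lineage cells. Csf1r, the receptor of macrophage growth factor (-3.35), the transcription factor Irf8 (-3.02) and Cebpa, a myeloid factor (-0.77), fell too. The list mean was -1.28 (adjusted p = 1.81e-16, and adjusted p = 0.216 with an estimated correlation). Mpo, a granule enzyme, differed by -0.54 (adjusted p = 0.183) and passed without T lineage array 2 (-0.97, adjusted p = 0.0249).

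Of 25 stem and progenitor genes 7 rose, 11 fell and 7 did not pass, with 8 higher and 11 lower when adjusted over the list alone. Flt3, a cytokine receptor of early progenitors, fell by 4.00 (SE 0.13), and so did the transcription factors Lmo2 (-1.68), Hoxa5 (-1.08), Spi1 (-1.06) and Meis1 (-0.98). Kit rose by 0.58 (adjusted p = 0.00546), which was lost without T lineage array 2 (0.0601, range 0.0016 to 0.0601). The list did not pass (mean -0.28, adjusted p = 0.0783), and it passed without T lineage array 2 (0.0274) and with a second quantile normalization (0.0464), over a range of 0.0274 to 0.606. Of 15 lymphoid priming genes 2 rose, 7 fell and 6 did not pass, with 2 higher and 8 lower when adjusted over the list alone. Ly6d, a marker of lymphoid progenitors (-1.63), and Lsp1 (-1.47) fell. The list fell with a mean of -0.41 (adjusted p = 0.00209, and adjusted p = 0.231 with an estimated correlation), which was lost without T lineage array 2 (mean -0.25, adjusted p = 0.0908) and without the dimmest 40% of probesets (0.0579), over a range of 8.88e-05 to 0.231. Il7r, the interleukin-7 receptor, fell by 0.95 (adjusted p = 0.00806), lost without T lineage array 2 (-0.57, adjusted p = 0.0698, range 0.000885 to 0.0698).

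Of 26 NK and innate lymphoid genes 5 rose and 8 fell, also when adjusted over the list alone. Gzma and Gzmb, both proteases of cytotoxic granules (2.33 for Gzmb), and Zbtb16, a factor of innate lymphocytes (1.09), rose, while Klrk1, an activating receptor (-3.93), and the regulator Id2 (-2.37) fell (list mean -0.29, adjusted p = 0.268). Of 23 B lineage genes 2 rose and 6 fell, also when adjusted over the list alone, with Blnk at -2.04 and Bst1 at -1.65, while Ebf1, a B lineage factor, did not pass (-0.14, adjusted p = 0.522). That list did not pass (mean -0.15, adjusted p = 0.0689), and it passed without wildtype lineage-negative array 1 (0.0194) and with a second normalization (0.0414), over a range of 0.0194 to 0.606. Mast cell and basophil genes rose in 2 and fell in 3 of 18 cases, with 2 higher and 4 lower when adjusted over the list alone. Cpa3, a mast cell protease, rose by 2.39 and Csf2rb, a cytokine receptor chain, fell by 2.42 (list mean -0.05, median 0.03, adjusted p = 0.759). Of 17 erythroid and megakaryocyte genes 2 rose and 2 fell, with 2 higher and 4 lower when adjusted over the list alone, among them the integrin Itga2b (1.32) and the carbonic anhydrase Car2 (-1.34, list adjusted p = 0.86). Of 31 stromal genes 1 rose (Timp3, 0.98) and 1 fell, also when adjusted over the list alone (list adjusted p = 0.693). For the 4 measured sex-linked genes 0 passed (list adjusted p = 0.78).

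Cell cycle genes went both ways. Of 23 DNA replication genes 6 rose and 0 fell, with 7 higher when adjusted over the list alone and Gins2, a replication fork subunit, at 0.67 (list mean 0.21, adjusted p = 0.000776, and adjusted p = 0.606 with an estimated correlation). Of 24 mitotic genes 0 rose and 6 fell, also when adjusted over the list alone, with Kif23, a kinesin of cell division, at -0.65 and Cenpf, a kinetochore protein, at -0.50. The mitotic list fell with a mean of -0.12 (adjusted p = 0.0239, and adjusted p = 0.606 with an estimated correlation). That call was lost without wildtype lineage-negative array 3 (0.091), T lineage array 2 (0.0569) or the dimmest 40% of probesets (0.14), over a range of 0.00772 to 0.606. Interferon response genes fell in 12 and rose in 1 of 22 cases, with 12 lower and 2 higher when adjusted over the list alone. Ifi27l2a (-1.65) and the antiviral GTPase Mx2 (-1.42) fell (list mean -0.47, adjusted p = 6.42e-06, and adjusted p = 0.35 with an estimated correlation).

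Homing and chemokine receptors fell in 11 and rose in 2 of 19 cases, also when adjusted over the list alone. Ccr2, a receptor of monocytes (-2.34), and Cx3cr1 (-1.17) fell, while Cxcr5, a receptor of follicular lymphocytes, rose by 1.85 (list mean -0.42, adjusted p = 0.000599, and adjusted p = 0.136 with an estimated correlation). Without the dimmest 40% of probesets the mean of this list was -0.77 (adjusted p = 0.000187, range over alternatives 0.000187 to 0.136). Of 20 immediate early and heat shock genes 2 rose and 5 fell, with 3 higher and 5 lower when adjusted over the list alone, among them Zfp36, which destabilises messenger RNA (-1.57), and the chaperone Hsph1 (0.53, list adjusted p = 0.241). Of 15 apoptosis regulators 2 rose and 5 fell, with 2 higher and 6 lower when adjusted over the list alone. Bcl2l1, an inhibitor of apoptosis, rose by 1.26 and Bcl2l11, a promoter of it, fell by 0.76 (list adjusted p = 0.325). For the apoptosis list the median was 0.02 over genes and -0.11 over probesets, against a mean of -0.04. Without T lineage array 1 or array 2 the 1670 higher calls of this comparison became 1035 and 1009. Of the 22 lists 10 passed with the preset and 0 with the estimated correlation. With fry, 12 lists moved on balance one way, the smallest adjusted p being that of dendritic cell genes (0.000242), and 21 changed in either direction.

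**Figure D2:**
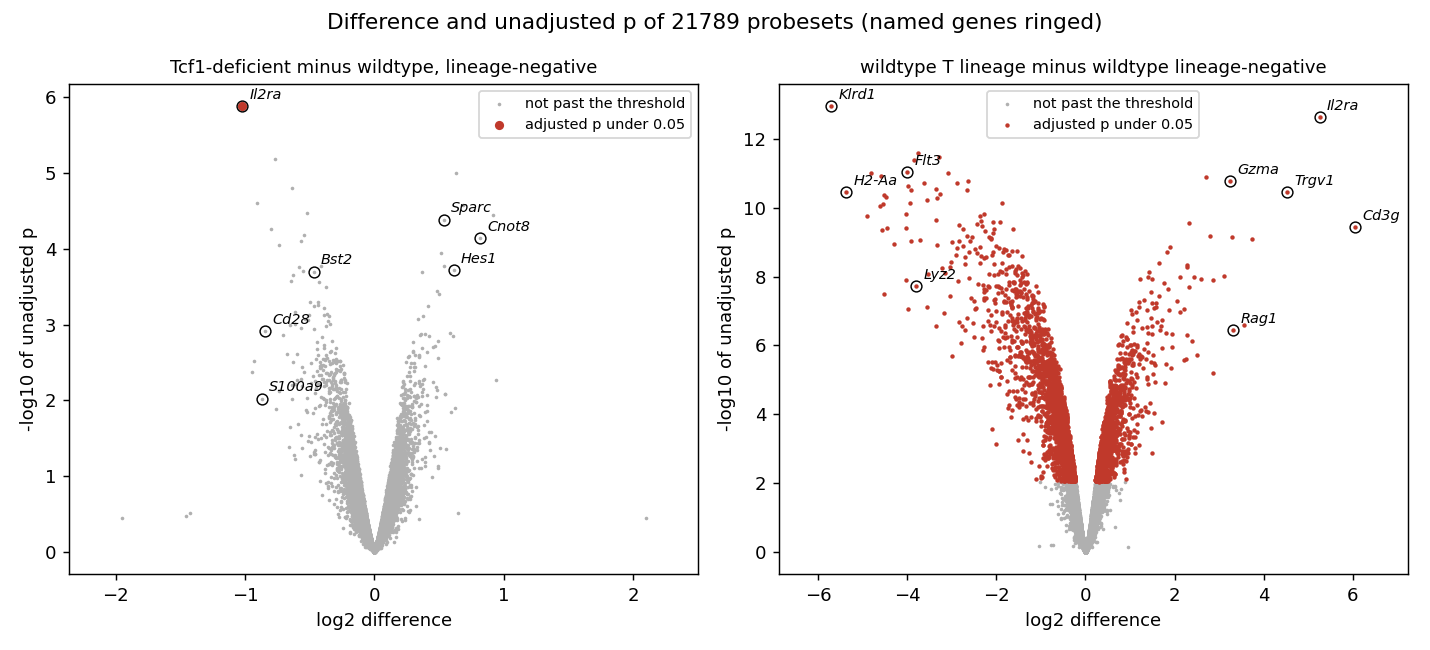
Log2 difference (horizontal axis) against -log10 of the unadjusted p (vertical axis) for each tested probeset between the genotypes (left) and between T lineage and wildtype lineage-negative cells (right), with probesets of adjusted p under 0.05 coloured. The left panel holds 1 coloured point, Il2ra at -1.02, and the right panel 3928.

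Against deficient lineage-negative cells, T lineage cells showed many of the same changes. Il2ra rose by 6.28, Cd3g by 5.79, Trgv1 by 5.18, Thy1 by 3.72 and Plxdc2 by 3.65. The largest falls were those of H2-Aa (-5.31), Klrd1 (-5.24), H2-Ab1 (-4.74), Nucb2 (-4.62) and Ifi205 (-4.46). Gata3 (1.57), Bcl11b (0.44), Rag1 (3.13), Flt3 (-3.77), Lyz2 (-3.23) and the progenitor marker Cd34 (-1.51) passed as well. Hes1 (0.14, adjusted p = 0.522), Kit (0.23, adjusted p = 0.256) and Il7r (-0.58, adjusted p = 0.0904) did not, and Il7r passed without T lineage array 1 (-0.96, adjusted p = 0.0078).

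In this comparison 3081 probesets passed, 1302 higher and 1779 lower (2924 genes), and 569 of them at least 2-fold. After a second quantile normalization 1653 were higher and 1701 lower. Higher calls were 816 without deficient array 1, 802 without T lineage array 1 and 789 without T lineage array 2. The same 23 dendritic cell and MHC class II genes gave 19 lower and 0 higher (adjusted p = 1.32e-28, and adjusted p = 0.136 with an estimated correlation). Granulocyte and monocyte genes gave 21 lower and 2 higher of 37 (4.38e-17, and adjusted p = 0.216 with an estimated correlation). Stem and progenitor genes gave 10 lower and 4 higher of 25, and that list passed here (mean -0.37, adjusted p = 0.00166, and adjusted p = 0.463 with an estimated correlation). Notch targets gave 5 higher and 0 lower of 16 (mean 0.62, adjusted p = 0.0112, and adjusted p = 0.353 with an estimated correlation), a call lost without Il2ra (mean 0.24, adjusted p = 0.0827), against a range of 0.00455 to 0.353 over the alternatives that kept it. TCR genes gave 14 higher and 4 lower of 26 (mean 0.63, adjusted p = 0.0112, and adjusted p = 0.606 with an estimated correlation), but without the dimmest 40% of probesets the direction of the test turned (mean 0.04, adjusted p = 0.98, range 1.94e-05 to 0.98). The probesets dropped there included those of Cd3g and Cd3d. T lineage transcription factors gave 8 higher and 1 lower of 21 (adjusted p = 0.0208, and adjusted p = 0.606 with an estimated correlation), lost without T lineage array 1 (mean 0.16, adjusted p = 0.0926), where the mean had been 0.24. DNA replication genes gave 3 higher and 0 lower of 23 (0.00211, and adjusted p = 0.606 with an estimated correlation), lost without T lineage array 2 (0.0558). Lymphoid priming genes gave 7 lower and 2 higher of 15 (mean -0.40, and -0.25 without T lineage array 2, adjusted p = 9.38e-05, and adjusted p = 0.182 with an estimated correlation), interferon response genes 9 lower and 1 higher of 22 (8.01e-05, and adjusted p = 0.358 with an estimated correlation), and homing receptors 11 lower and 2 higher of 19 (mean -0.40, and -0.75 without the dimmest 40% of probesets, adjusted p = 2.44e-05, and adjusted p = 0.136 with an estimated correlation). Mitotic genes, a list that passed against wildtype cells, did not pass here (3 lower of 24, adjusted p = 0.175, but 0.035 without deficient array 2, range 0.035 to 0.772), while the stem and progenitor list, which did not pass against wildtype cells, passed. B lineage genes (adjusted p = 0.0545) passed without deficient array 3 (0.0263) or wildtype lineage-negative array 1 (0.0463), with a second quantile normalization (0.0412) and with median centring (0.0464), over a range of 0.0263 to 0.606. V(D)J recombination genes (0.275) passed without T lineage array 2 (mean 0.61, adjusted p = 0.0106, range 0.0106 to 0.772) and immediate early genes (0.129) without T lineage array 1 (0.0407, range 0.0407 to 0.606). Mean and median differed in sign for V(D)J recombination, NK, mast cell and stromal genes, of which none passed as a list with all arrays. With fry, 13 lists moved on balance one way and 21 changed in either direction. Of the 22 lists 10 passed with the preset and 0 with the estimated correlation.

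The T lineage comparisons shared most of their calls. Of the probesets called in both, 1120 were higher in each (chance 99.8), 1663 lower in each (chance 184) and 0 opposite, with 1145 called against wildtype cells alone and 298 against deficient cells alone. Whether the effects of these differ was tested only by the genotype comparison. Across probesets, which are not independent, the differences correlated with r = 0.965, against a median of 0.599 in 100 simulations with the same shared T lineage arrays. All groups were unchanged in these simulations, so the correlations are not directly comparable. The covariance of the differences was 0.153, against 0.00694 in the simulations.

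Between the genotype comparison and the T lineage comparison against wildtype cells, 1 probeset was called in both, that of Il2ra, lower in deficient cells and higher in T lineage cells (chance 0.0766). Its protein, CD25, defined the T lineage gate, so its call there followed from the sort. The chance value is therefore no test of this overlap. This overlap was 4 without deficient array 1, 11 without wildtype lineage-negative array 1, 2 without T lineage array 2, and 0 without deficient array 3 or wildtype lineage-negative array 2 or 3. At an unadjusted p under 0.05, 407 of the 670 probesets lower in deficient cells were also called lower in T lineage cells, and 116 of the 401 higher in deficient cells were called higher. Opposite directions held 26 and 12. Independent lists would give 69.4 and 30.7 in the same direction. In 100 simulations with deficient and wildtype cells alike, the same shared arrays and the T lineage differences at their measured size, the share of lower probesets called lower was 19.9% to 29.6% (60.7% observed) and of higher ones called higher 25.9% to 37.3% (28.9% observed). The share of higher ones called lower was 10.3% to 16.8% (6.48% observed) and of lower ones called higher 7.25% to 12.3% (1.79% observed). Genes varied independently in these simulations. An array that shifts many genes together could move the shares further, so they do not separate an effect of the genotype from variation between arrays. Both comparisons subtract the same 3 wildtype arrays. Their correlation over probesets was r = 0.423, and simulations with all groups unchanged gave a median of 0.446. The measured T lineage differences widen the spread that r divides by, so these correlations cannot be set against each other. The covariance of the comparisons was 0.0193, against a median of 0.00461 and at most 0.00589 in the simulations of unchanged groups. This leaves 0.0147 beyond what the shared arrays give where genes vary independently.

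**Figure D3:**
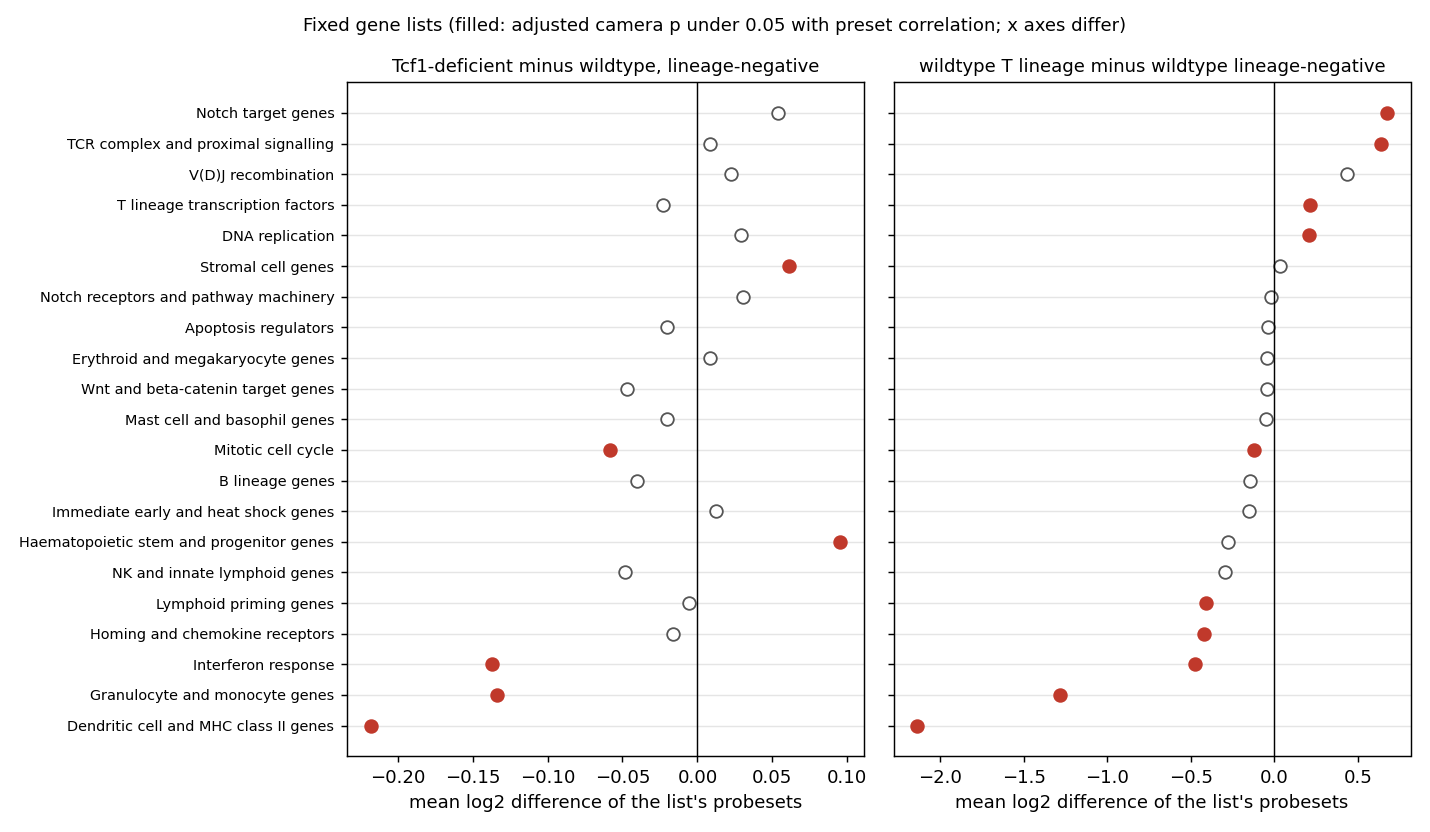
Mean log2 difference of each fixed list except the sex-linked genes (horizontal axis) for the genotype comparison and for the T lineage comparison against wildtype lineage-negative cells. Lists with an adjusted camera p under 0.05 at the preset correlation are coloured, and no list passed with an estimated correlation. The dendritic cell and MHC class II list has means of -0.22 and -2.14.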

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

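The sex covariate and leaving the gate genes out of the lists were chosen only after the data were seen, and the other alternatives were planned. Between the lineage-negative groups the call count of 1 (0 higher, 1 lower) became 2 when only the 2 groups compared were fitted (1 higher), 0 with all probesets (0 lower), 3 with probesets averaged per gene (1 higher, 2 lower), 3 with a second quantile normalization (1 higher, 2 lower), 0 with median centring (0 lower), 11 with trend and robust settings (5 higher, 6 lower), 6 with array weights (2 higher, 4 lower) and 2 with the sex covariate (1 higher). Leaving out 1 array gave 0 to 12 calls (0 to 1 higher, 0 to 11 lower), and the overlap with the T lineage comparison ranged from 0 to 11 probesets. The second normalization gave an overlap of 2. Il2ra lay lower under each of its 17 alternatives, from -1.13 to -0.90, with adjusted p from 0.00539 to 0.219, and 0.268 with all probesets. The spread of calls from 0 to 12 leaves the number of genes that differ by genotype open, and its cause was not tested. Deviations of same-numbered deficient and wildtype lineage-negative arrays correlated at -0.13, 0.02 and 0.04, and those of unlike number at -0.11 to 0.08. Values this close to each other do not settle whether arrays of the same number shared a culture day or batch. For the 2 same-numbered pairs of T lineage and wildtype lineage-negative arrays the correlations were 0.158 and 0.12, and the labels give these no shared mouse or culture. Both arrays numbered 1 carried Y-linked transcripts and both numbered 2 carried Xist, so a shared mouse stays possible. Wildtype lineage-negative array 3 and deficient array 2 carried Y-linked transcripts, and deficient arrays 1 and 3 carried Xist. With a replicate block, the calls were 0 (0 lower), the overlap was 0, and the T lineage comparisons gave 3467 and 2680 calls. Between T lineage and wildtype lineage-negative cells the block ended the calls of Cd3e (adjusted p = 0.0655), Lef1 (0.101), Mki67 (0.058), Tyms (0.0662) and the mitotic list (0.0665) and made one of the B lineage list (0.038). Against deficient cells it ended those of Cd3e (0.0866), Lef1 (0.0818) and Chaf1a (0.0951) and made one of the B lineage list (0.0326). Between the genotypes it ended that of Il2ra (0.151) and made one of the Notch target list (0.0432).

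Against wildtype and deficient lineage-negative cells, the 3928 and 3081 T lineage calls stayed within 1.5 times under each alternative. Higher calls ranged from 1009 to 1721 and from 789 to 1362 with 1 array left out, where a lone T lineage array was assumed to vary like the other groups. Of the 4614 gene values under alternatives, 58 changed sign without either value passing the test. Calls of named genes were lost in 5, 41 and 58 cases in the 3 comparisons, and gained in 0, 2 and 2. The 26 list calls fell to 0 with the estimated correlation, and the cause was not tested. The TCR list between T lineage and deficient lineage-negative cells turned in the direction of its test, though not of its mean, when the dimmest 40% of probesets were dropped (mean 0.0407, adjusted p = 0.98, range over alternatives 1.94e-05 to 0.98). That filter ranked probesets by their mean over all 8 arrays, most of them lineage-negative. It removed Cd3g (5.08 in deficient and 10.87 in T lineage cells) and Cd3d (5.32 and 8.10), which rose strongly. How much of the turn these account for was not tested. Signal over background was not used here, so the limit it sets on dim genes is unknown.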

Other observations

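The gene families, the sex covariate and the tests of residual T lineage cells, of the dendritic cell-like share and of the neighbourhood of the targeted locus, with the splits for the latter pair, were chosen only after the results were seen. The 14 families were picked after large changes of some of their members were seen, so their counts describe these data and test nothing about a family as a whole, and some members stand in the fixed lists too. Between T lineage and wildtype lineage-negative cells, 7 of 8 genes of the Gimap family, GTPases of lymphocytes, rose and 0 fell, with Gimap1 at 1.78, Gimap9 at 1.49 and Gimap5 at 1.30. Of 10 Toll-like receptors, which sense microbial molecules, 6 fell and 0 rose, with Tlr7 at -2.27, Tlr3 at -1.97 and Tlr1 at -1.81. Of 10 genes of the Ifi200 family, interferon-induced sensors of DNA, 6 fell and 0 rose, with Ifi207 at -3.18 and Ifi209 at -3.16. Cathepsins, proteases of the lysosome, fell in 8 and rose in 2 of 21 genes, with Ctss at -4.03 and Ctsb at -1.33, while their median was 0.00.

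C-type lectins fell in 17 and rose in 3 of 34 probesets, with Clec12a at -1.86 and Clec4e, a sensor of damaged cells, at 1.57. Killer cell lectin-like receptors fell in 8 and rose in 0 of 23 genes, with Klra17 at -3.35 and Klri2 at -2.56, and 7 fell after a second quantile normalization. S100 proteins fell in 8 and rose in 2 of 15 probesets. Among 10 granzymes 2 rose and 0 fell (Gzma and Gzmb), and among 9 aldo-keto reductases of the 1C group 2 rose and 0 fell, Akr1c12 at 3.12 and Akr1c13 at 2.27. Interferon-induced transmembrane genes rose in 5 and fell in 1 of 10 probesets, histones rose in 13 and fell in 4 of 43, Hox genes rose in 4 and fell in 3 of 40, Fc receptors fell in 2 of 7 and ribosomal proteins rose in 1 of 207. Except for the killer receptors, the S100 proteins, the histones and the ribosomal proteins, the counts were the same after a second quantile normalization and after median centring. Between the genotypes limma called 0 of the 447 probesets of these families, and 1 of all 21789, and 28 of the 447 (6.26%) had an unadjusted p under 0.05, as had 4.92% of all.

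For Il2ra, the gene called between the genotypes, the 10 splits of the 6 lineage-negative arrays are too few for a share under 0.05, and the real split gave 1 call and the highest of the others 0. For a donor strain segment around the targeted locus, the test rested on a single call, which lay outside the 10 Mb window (one-sided Fisher exact p = 1). Il2ra lies on another chromosome, where such a segment could act only from a distance, and this the test cannot address, so it stays open. The sex of the mice as the whole cause is argued against, because the Y-linked genes differed by -1.61 between the genotypes and yet the sex covariate left Il2ra at -1.06 (SE 0.10, adjusted p = 0.0316). Residual T lineage cells in the wildtype sort, of which a share of 1.32% would suffice but which the gate against Thy1 and CD25 would remove, may still account for it: the shift of 19 bright T lineage genes was 0.723 (SE 0.25) of the size needed, but 0.285 (SE 0.30) without Trgv1 and 0.172 (SE 0.12) over all 25 genes. Single genes went different ways. Trgv1 lay 0.65 higher in wildtype than deficient cells (0.57 predicted), and Thy1 differed by -0.02 (SE 0.16, 0.23 predicted). Cd3g, dimmer than Il2ra, differed by -0.27 (SE 0.24, 0.79 predicted). An effect of the genotype on Il2ra stays open as well, and it and residual T lineage cells cannot be told apart with so few bright genes.

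The dendritic cell and MHC class II list was lower in deficient cells by 0.218. The 10 splits are again too few for a share under 0.05, and 2 of them gave a mean as large, the highest of the others 0.235. Over all lists the real split called 6 and the other 9 splits from 3 to 8, with 4 of these at 6 or more. A lower share of dendritic cell-like cells in the deficient cultures, which the gates against Mac1 and Gr1 would remove only in part, could give such a shift. The 9 markers at least 4-fold lower in T lineage cells did not move by unequal amounts that a chi-square test resolved (p = 0.164, weighted mean -0.16), with H2-Aa at -0.06, Itgax at -0.07, Siglech at -0.54 and Xcr1, the one not lower, at 0.05 (SE 0.18), so this and an effect of the genotype within cells cannot be told apart.

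Near the targeted locus, within 10 Mb, 6 of 280 probesets (2.14%) had an unadjusted p under 0.001, against 40 of 21509 elsewhere (0.186%, one-sided Fisher exact p = 2.6e-05), and none of the 6 had an adjusted p under 0.05. They were 1810065E05Rik (0.63), Sparc (0.54), Fam114a2 (-0.34), Zfp672 (-0.46), Zfp39 (-0.54) and Cnot8 (0.82), 3.15 to 6.64 Mb away, with adjusted p from 0.0725 to 0.466; under alternatives Cnot8 was called in 4 of 18 (adjusted p from 0.0194 to 0.651, and 0.0194 without either T lineage array), 1810065E05Rik in 4 of 17 (0.0303 to 0.471) and Zfp39 in 1 of 18, without wildtype lineage-negative array 1 (0.049, range to 0.651). Other probesets of 2 of these genes moved less, so that averaged per gene Cnot8 differed by 0.48 (adjusted p = 0.19) and Zfp672 by -0.23 (adjusted p = 1). The real split gave 6 such probesets and the highest of the other 9 splits 1, but 1 in 10 splits is the smallest share this design allows. A further gene within 10 Mb, H2aw, was the only call between the genotypes without wildtype lineage-negative array 2. A candidate explanation is a donor strain segment that came with the targeted allele, given the mixed background the labels state, or an effect of the targeting on its neighbours, and the data do not separate these from an effect of Tcf1 itself.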
